A study of Mus musculus with 8 samples.

How the data were processed

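RNA from the epididymal fat of 20 male mice aged 42 days was pooled for each of 4 mouse lines, DU6, DU6i, DUKs and DBA, and each pool was hybridised to 1 Affymetrix chip A array and 1 chip B array (8 arrays). The chips carry different probe sets, 6584 on chip A and 6595 on chip B, apart from a small group placed on both. Outside that group a pool has 1 value per probe set. Per the labels, labelled cRNA was made by in vitro transcription from a T7-oligo(dT) primer. Per the labels, the authors calculated the intensity of each probe set with Microarray Suite 4.0.1 and Data Mining Tool 1.2 and scaled each array over all its probe sets. The deposited intensity values are linear, and between 12.8% and 30.5% of them per array lie below 0. Their mean between the 2nd and 98th percentile was 2500 on each of the 8 arrays. That these intensities are average differences between perfect-match and mismatch probes is the practice of that software and is not stated in the labels. Detection calls were not used here. A pool hides the differences between animals, and scaling to one overall level fixes the mean of an array but not the range of its signals.

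Probe sets were named through the platform annotation supplied with the files. On chip A 5560 probe sets had 1 gene symbol, 197 had several and 827 were unnamed here; on chip B these numbers were 2001, 27 and 4567. The named probe sets covered 6137 genes. Symbols were updated through a table of mouse genes, and no coordinates were used. The 110 control probe sets with AFFX in their name were left out of the comparisons, which left 13069 probe sets. Others placed on both chips, such as MURINE_B2_at and YEL002c/WBP1_at, stayed in, once for each chip. Where a gene had several probe sets, the one with the highest mean signal over the 4 arrays was used.

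A floor was set for each chip at the 95th percentile of the sizes of its negative signals, which gave 1022.8 for chip A and 2258.25 for chip B. Signals at or under the floor were set to it before log2 was taken, and a probe set entered a pair of lines when at least 1 of the 2 arrays was above the floor. A ratio against a signal at or under the floor is written as "at least". A probe set was counted as higher or lower at 2-fold or more, a rule of size and not a test. Arrays were compared only within a chip.

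DU6 with DUKs and DU6i with DBA were the main pairs, DU6 with DU6i and DUKs with DBA the pairs within a side of the series title. No test and no p-value is possible for a pair, because each line has 1 pool. The only test was limma's (lmFit and eBayes) of DU6 and DU6i against DUKs and DBA, with 2 lines per side. It used probe sets above the floor on at least 2 of the 4 arrays, and was repeated for comparison on the other splits of the lines. Chips were fitted separately and p-values adjusted over both (Benjamini-Hochberg, 0.05). An exact permutation test of 2 lines against 2 cannot give a p under 1 in 3. Its spread is between lines, and DU6i was derived from DU6, so the lines are not independent. On simulated data with 5267 probe sets and the median SD between the 4 lines (0.327), the same limma code called 100% of 4-fold, 44.8% of 2-fold and 3.03% of 1.5-fold differences, and 0.197% of unchanged probe sets. Every probe set had the same spread there, so that power in the real data, where spreads differ, was not measured.

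The technical error was taken from genes with 2 probe sets above the floor on both arrays of a pair. The SD of a single log2 ratio derived from them was 0.44 for DU6 vs DUKs (387 genes) and 0.34 for DU6i vs DBA (383 genes). It covers differences between probe sets within a hybridisation or between the chips, not differences between animals or pools. Of the probe sets placed on both chips, 17 were above the floor on all 8 arrays. Their log2 ratios on the chips differed by a median of 0.25 in DU6 vs DUKs and 0.28 in DU6i vs DBA. The largest such differences were 1.04 and 0.80.

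Gene lists, 36 in number, and a set of sentinel genes were fixed before the data were examined. For each list with at least 3 measured genes, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these arrays and is not a p-value. A list was called high or low above percentile 97.5 or below percentile 2.5. On simulated lists of 20 genes shifted by 0.4 in log2, 74% passed the upper limit.

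Named genes followed a rule also fixed before the data were examined. It takes the 10 genes higher and 10 lower with the largest smallest difference between the sides, the 10 highest and 10 lowest of each main pair measured on both arrays with the 5 largest bounds in each direction, and the 5 highest and 5 lowest of each other pair. List members at 2-fold or more in a main pair and all sentinel genes were added, which gave 188 genes.

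Other settings chosen before the data were examined were rescaling to one trimmed mean, quantile normalisation, a floor halved or doubled, log2(signal + floor), 3-fold, both arrays above the floor, probe sets of the plain _at kind, no filter, an intensity trend, leaving out each line, lines paired as a block, and the mean over all probe sets of a gene. Pairs matched on 5' control signal, 1 chip alone, leaving out probe sets brighter than 10000, and a second probe set of a gene were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.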

Results

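Transcript levels in epididymal fat, the fat pad beside the epididymis of the male mouse, were measured in 4 mouse lines on Affymetrix arrays. DU6 is a line selected over many generations for high body weight, DU6i an inbred line derived from it, and DUKs an unselected control line; DBA is an inbred strain. This account of the lines is general knowledge; the labels speak only of selected lines, adiposity, diabetes, insulin and leptin. The series title sets DU6 and DU6i against DUKs and DBA. Each line was 1 pool of 20 males aged 42 days on 1 chip A and 1 chip B array, so there was no replicate of any line, and the number of arrays limits the precision. Between 3045 and 3334 probe sets of chip A and between 1639 and 1823 of chip B were above the floor on an array.

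The pools differed in their signal toward the 5' end of a control transcript. For pyruvate carboxylase, whose control probe sets lie along the mRNA, the middle probe set had 15.3% of the 3' signal in DU6 and 19.5% in DBA on chip A, against 54.5% in DU6i and 53.9% in DUKs. On chip B these values were 12.7%, 14.3%, 45.3% and 55.6%. This split of the lines crosses both main pairs, in opposite directions. It rests on pyruvate carboxylase, and pairs called matched on 5' control signal are matched on this transcript alone. The 3' to 5' ratio of actin was 2.12, 2.46, 1.73 and 2.33 on chip A in DU6, DU6i, DUKs and DBA. That of Gapdh was 0.90, 1.03, 1.18 and 1.22. On chip B they were 2.75, 1.72, 1.66 and 1.90 for actin and 1.44, 0.90, 1.41 and 0.86 for Gapdh. Only actin on chip B set DU6 and DBA apart from DU6i and DUKs. The ranges of signal differed as well. On chip A the 99th percentile of the signals was 18810 in DU6, 23450 in DBA, 27552 in DUKs and 34793 in DU6i, and on chip B it was 49489, 33621, 52203 and 34692 in the same order.

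**Figure D1:**
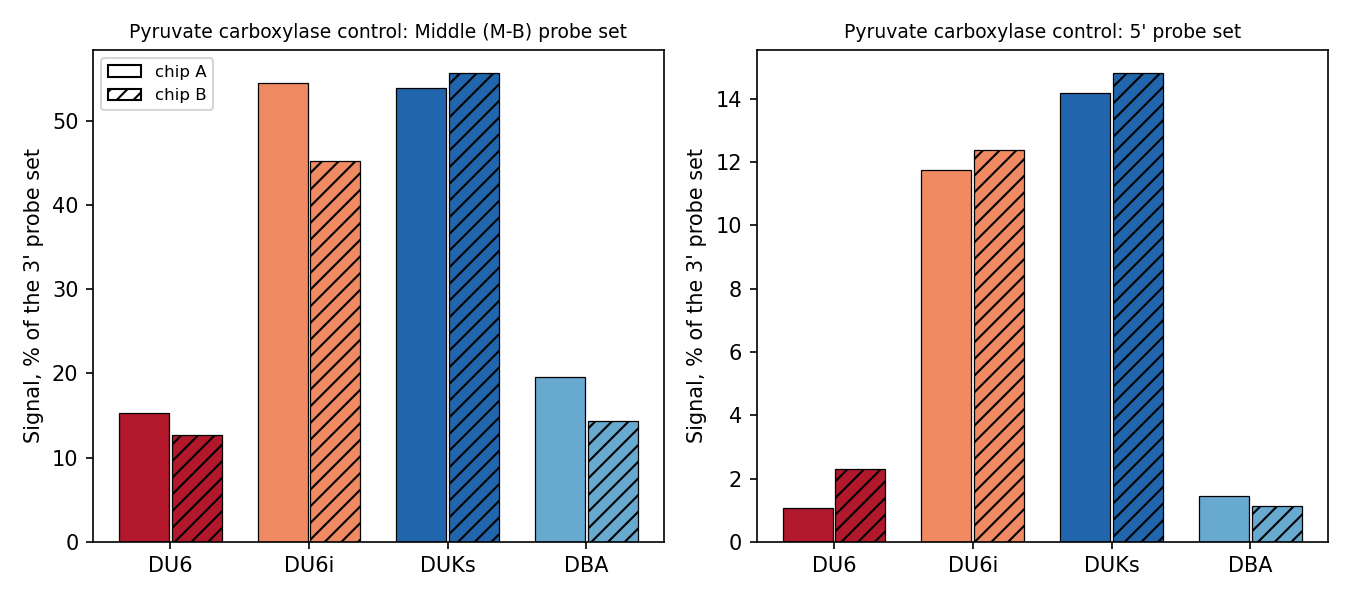
Signal of the middle (left) and 5' (right) control probe sets of pyruvate carboxylase as a percentage of its 3' probe set, 1 bar per array, plain for chip A and hatched for chip B. On both chips the middle probe set reached 12.7% to 19.5% in DU6 and DBA and 45.3% to 55.6% in DU6i and DUKs.

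The first comparison asked how the fat of the selected DU6 line differs from that of the control line DUKs. Among the genes lowest in DU6, Dnajb3, a DnaJ family member, was 14.4-fold lower and Hspa4l, of the Hsp70 family, 7.93-fold. Ldhc, the testis form of lactate dehydrogenase, was 6.69-fold lower. These genes were also lower in DU6i than in DBA at 2-fold or more. Dnajb3 and Hspa4l were higher in DUKs than in DBA, as were 13 of 15 genes of the testis and germ cell list. Whether their transcripts came from germ cells in the pools was not tested. Ifi27, an interferon-induced gene, had a signal of 3127 in DU6 and 33667 in DUKs, a 10.8-fold difference. Higher in DU6 were Thy1 (3.72-fold), the serine protease Htra3 (3.53-fold), the matrix proteoglycan Fmod (3.17-fold), Sod1 (2.93-fold) and the metalloproteinase inhibitor Timp1 (2.83-fold). Adig, a gene of adipocytes, had a signal of 8680 in DU6 and was under the floor in DUKs, at least 8.49-fold higher. Ntsr2 was at least 8.27-fold higher and was under the floor in the other 3 lines.

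Of the genes of fat metabolism, Lpl, which releases fatty acids from circulating triglyceride, was 2.73-fold lower in DU6 than in DUKs, and Lipe, the hormone-sensitive lipase, 2.04-fold lower. Fabp5, a fatty acid carrier, was 2.38-fold higher, Decr1, of fatty acid oxidation, 2.73-fold higher, and Thrsp, linked to fatty acid synthesis, 2.01-fold higher. Fasn, the fatty acid synthase, differed by a log2 ratio of only -0.04. Of the list of mature adipocyte markers, 13 of 17 measured genes lay lower in DU6, with a median log2 ratio of -0.68 (percentile 0). After quantile normalisation this median was -0.17 (percentile 0.80), and the 11 list members on chip A had a median of -0.80 against -0.12 for the 6 on chip B.

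Markers of macrophages and myeloid cells lay higher in DU6 in 24 of 26 measured genes, with a median of 0.47 (percentile 99.99). Among them were Hmox1 (2.39-fold), the lectin Lgals3 (2.38-fold), Mpeg1 (2.16-fold) and the receptor Csf1r (2.08-fold); S100a9 was at least 2.10-fold lower. Extracellular matrix genes had a median of 0.30 (percentile 99.6), with 5 of 43 at 2-fold or more higher and 1 lower, the higher ones including Tnxb at 2.21-fold (log2 ratio 0.79 by a second probe set). The matrix median was 0.39 (percentile 99.88) for the 21 genes on chip A and 0.13 (percentile 54.85) for the 22 on chip B. Endothelial markers had a median of 0.45 (percentile 98.3), although Cd34 was at least 2.97-fold lower. Immediate early genes had a median of 0.44 (percentile 98.8), with the transcription factor Cebpb at least 3.23-fold higher; after quantile normalisation the percentile was 97.1. On the low side were interferon-induced genes (15 of 18 lower, median -0.35, percentile 0.27), antigen presentation genes (median -0.31, percentile 1.37), lymphocyte markers (median -0.39, percentile 2.14) and genes of glucocorticoid and steroid metabolism (median -0.57, percentile 0.51). The members of the last list at 2-fold or more lower were the steroidogenic enzymes Cyp17a1, also in the testis and germ cell list, and Hsd3b1; the median of the testis and germ cell list was -1.73 in the same pair. The median of ribosomal protein genes was -0.29 (percentile 0.665) and turned to 0.05 after quantile normalisation. The lymphocyte median came from few genes, had percentile 2.75 after quantile normalisation and turned to 0.94 on chip B alone.

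In all, 219 probe sets were at least 2-fold higher in DU6 and 353 at least 2-fold lower, of 5604 measured. These are counts by size with no test. Of 31 such calls with a second probe set of the gene, 20 had the same direction there and 10 were also 2-fold. Akap1, at least 9.14-fold lower by 1 probe set, had a log2 ratio of 0.12 by another.

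The second pair sets the inbred DU6i line against DBA. Lep, which encodes the adipocyte hormone leptin, had a signal of 27777 in DU6i and 3837 in DBA, a 7.24-fold difference. Ghr, the growth hormone receptor, was at least 6.95-fold higher in DU6i, Cryab, a small heat shock protein, at least 5.45-fold, Sptbn1 4.70-fold and Psmb6, a proteasome subunit, 4.39-fold. Abcd2, a transporter of peroxisomes, was 3.80-fold higher. Lower in DU6i were the amino acid transporter Slc38a5 (12.7-fold), C4bp, of the complement system (11.3-fold), Cad, of pyrimidine synthesis (9.06-fold), Amot (8.42-fold), Iigp1, an interferon-induced GTPase (7.82-fold), Hoxb6 (7.33-fold) and the desmosome gene Dsp (5.51-fold). The epididymis and male tract list was low in this pair as well (median -1.55, 9 of 13 genes at 2-fold or more lower). From which tissue in the pools the transcripts named here came was not tested. Pdxdc1 was 4.00-fold higher by 1 probe set and had a log2 ratio of -3.42 by another.

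Of the mature adipocyte markers, 15 of 17 lay higher in DU6i than in DBA, with a median of 0.86 (percentile 100). Retn, which encodes resistin, was 1.99-fold higher, Lipe 1.96-fold, Scd1, the stearoyl-CoA desaturase, 1.94-fold and Pparg, the main transcription factor of adipocytes, 1.88-fold. After quantile normalisation the list median was 0.35 (percentile 99.8), and the 11 members on chip A had a median of 0.93 against 0.29 (percentile 97.275) for the 6 on chip B. Genes of lipolysis and lipid storage lay higher in 12 of 12 measured genes (median 0.50, percentile 99.5). Adipokines (0.61, percentile 99.955), fatty acid and triglyceride synthesis (0.42, percentile 99.4), the citric acid cycle (0.38, percentile 97.8) and adipogenic transcription factors (0.24, percentile 98.5) were also on the high side. Me1, the malic enzyme, was 2.19-fold higher, Orm1 2.66-fold and the transcription factor Cebpa 2.14-fold, whereas Elovl6, a fatty acid elongase, was 2.03-fold lower. After quantile normalisation the adipokine median was 0.39 and that of fatty acid and triglyceride synthesis 0.28; on chip B alone they were 0.10 (percentile 61.95) and 0.20 (percentile 82.0), and that of adipogenic transcription factors was 0.15 (percentile 80.3). The citric acid cycle list lay inside the central 95% of random lists after quantile normalisation (percentile 93.7).

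Macrophage and myeloid markers lay higher in DU6i in 20 of 22 genes (median 0.66, percentile 100), with Ccl9 at 2.32-fold, Adgre1 at 2.20-fold, Cd68 at 2.19-fold, Lgals3 at 2.19-fold and Mrc1 at 2.15-fold. A second probe set of Lgals3 gave a log2 ratio of 0.20 there. Extracellular matrix genes had a median of 0.41 (percentile 100), with 6 of 40 at 2-fold or more higher, among them Postn (2.35-fold) and Col5a1 (2.31-fold). The medians of endothelial markers (0.51, percentile 99.89), smooth muscle and pericyte markers (0.47, percentile 99.35), skeletal muscle markers (0.67, percentile 99.96) and preadipocyte and stromal markers (0.27, percentile 97.88) were high as well. Mesothelial markers were low (median -0.77, percentile 0.10), led by the epithelial keratins Krt18 (3.85-fold lower), Krt7 (2.93-fold) and Krt8 (2.86-fold). Keratins are made by other epithelia as well, and the epididymis and male tract list had a median of -1.55 in the same pair (9 of 13 genes at 2-fold or more lower). On chip A alone the mesothelial median was -0.50 (percentile 4.885).

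DU6i had 266 probe sets at least 2-fold higher and 371 at least 2-fold lower than DBA, of 5556 measured. Without probe sets brighter than 10000 the higher ones numbered 169. Of 26 calls with a second probe set of the gene, 24 had the same direction there and 17 were also 2-fold.

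The 2 pairs share no array, so that genes called in both were counted. Higher in both were 14 probe sets of 5085, where independent lists would share 9.93, and lower in both 41, where 20.9 would be expected. At 2-fold in opposite directions were 85, against 29.0 expected. The 11 genes named among the 14 included Hfe, Slc6a13, Nid2, Sfrp2, Lgals3 and Gsto1. Of the 28 genes among the 41, 6 belonged to a germ cell list, Prm1, Prm2, Ldhc, Odf1 and Smcp among them. The lists do not hold every germ cell gene, so that 6 is a minimum. Genes outside the lists were not classed by tissue. Between DU6 vs DBA and DU6i vs DUKs, the pairs matched on 5' control signal, 26 were higher in both (6.58 expected), 49 lower in both (12.7 expected) and 59 opposite (19.5 expected).

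By gene list, 3 lists were high in both pairs (endothelial markers, extracellular matrix, macrophage and myeloid markers) and 2 low in both (testis and germ cell markers, epididymis and male tract markers). Mature adipocyte markers lay at opposite ends. In the pairs matched on 5' control signal they did not, with medians of 0.07 in DU6 vs DBA (percentile 66.1) and 0.51 in DU6i vs DUKs (percentile 99.9); after quantile normalisation the latter was 0.18 (percentile 89.4). Of 35 lists measured in both pairs, 12 were outside the central 95% in the first pair and 15 in the second, where random lists would give 1.75. In the pairs matched on 5' control signal the macrophage list was no longer high in both, since its median in DU6i vs DUKs was 0.28 (percentile 96.5). The macrophage list was also high within the sides, at 0.47 in DU6 vs DU6i (percentile 99.95) and 0.38 in DUKs vs DBA (percentile 99.91). The endothelial and extracellular matrix lists lay inside the central 95% in both of these pairs. After quantile normalisation the extracellular matrix list was no longer high in both main pairs, with a median of 0.23 in DU6 vs DUKs (percentile 95.8). Preadipocyte and stromal markers were then high in both main pairs (0.44, percentile 99.57, and 0.36, percentile 99.74). The endothelial list was not high in both with the floor halved, the floor doubled, log2(signal + floor) or chip A alone, where its median in DU6 vs DUKs was 0.30 (percentile 75.4). By chip B alone no list was high in both.

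**Figure D2:**
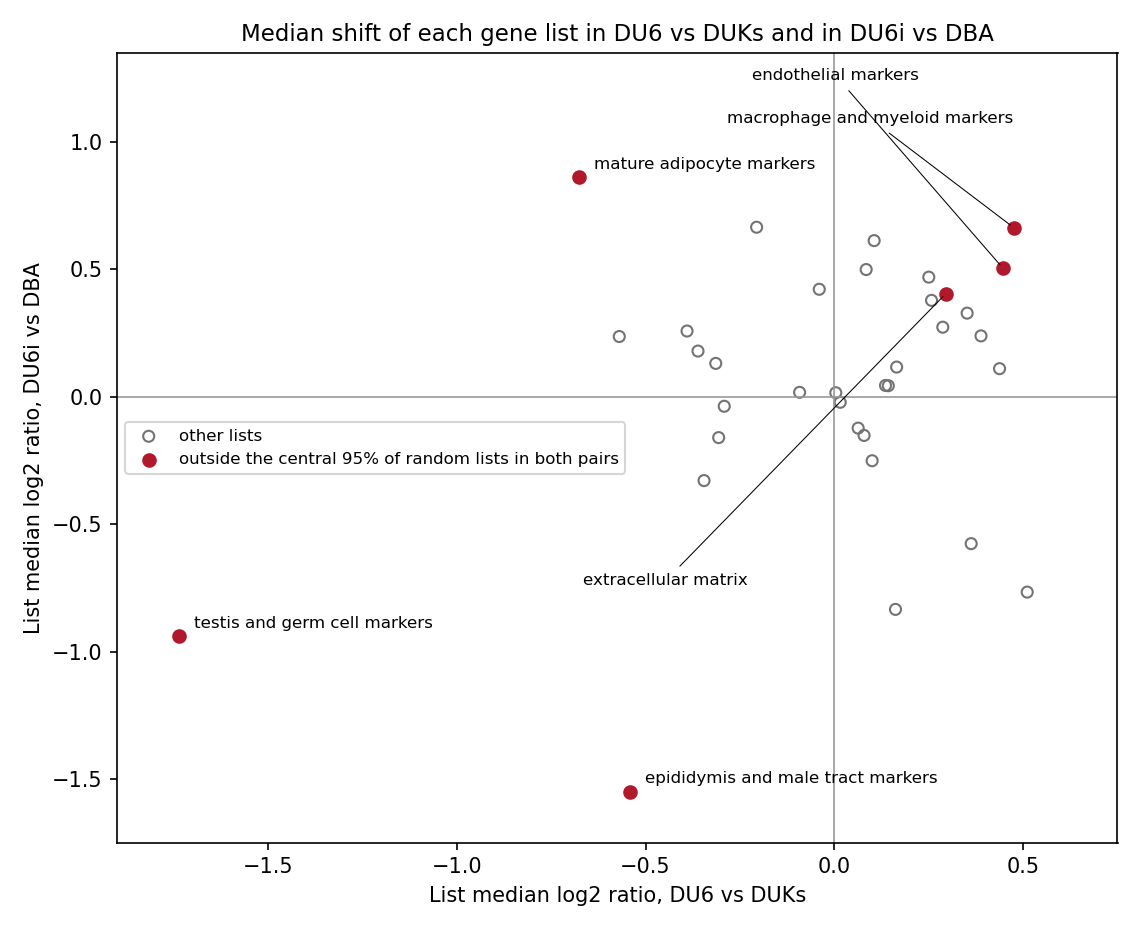
Median log2 ratio of each of 35 gene lists in DU6 vs DUKs (horizontal axis) and DU6i vs DBA (vertical axis), 1 point per list. Filled points lie outside the central 95% of random lists in both pairs. Testis and germ cell markers lie at -1.73 and -0.94, mature adipocyte markers at -0.68 and 0.86.

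Transcripts of germ cells were present in all 4 fat pools and highest in DUKs. Prm1, a protamine of the sperm nucleus, had a signal of 28545 in DUKs, 19113 in DBA, 8576 in DU6 and 8740 in DU6i. Tnp1, a transition protein of spermatids, had 47073, 20147, 14689 and 10822 in the same order. Of the 15 list genes above the floor on an array, 13 were highest in DUKs, and 12 of the 12 measured in DU6i vs DBA were higher in DBA. The list median was -1.73 in DU6 vs DUKs (13 of 15 genes at 2-fold or more lower, percentile 0) and -0.94 in DU6i vs DBA (5 of 12, percentile 0.01). Odf1, of the sperm tail, was 4.62-fold lower in DU6 than in DUKs and at least 6.32-fold lower in DU6i than in DBA.

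Genes of the male reproductive tract did not follow 1 order of the lines. Gpx5, the epididymal glutathione peroxidase, had signals of 49126 in DU6, 52044 in DUKs and 20753 in DBA, and was below 0 in DU6i. Adam7, of the epididymis, was 3.66-fold lower and Lcn2 5.31-fold lower in DU6i than in DBA. The seminal vesicle secretion genes Svs2, Svs4 and Svs5 were above the floor in DBA alone, with signals of 19922, 42807 and 43837. Sbp, which encodes a spermine-binding protein of the male glands, was above it in DUKs alone, at 21028, as was Spink1, at 5876. The list median was -0.54 in DU6 vs DUKs (percentile 0.71) and -1.55 in DU6i vs DBA (percentile 0).

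**Figure D3:**
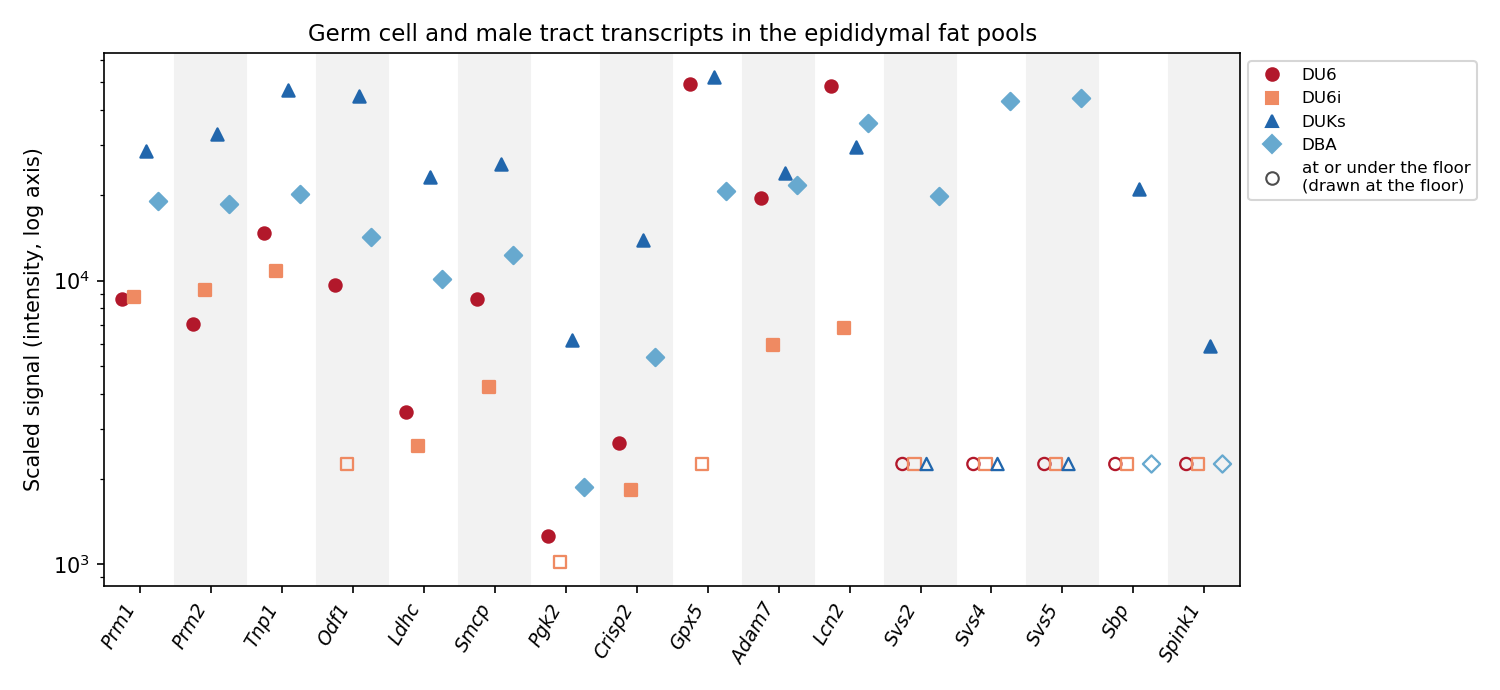
Scaled signal (log axis) of germ cell genes (Prm1 to Pgk2), Crisp2 and male tract genes (Gpx5 to Spink1), 1 point per line. Open points lie at or under the floor and are drawn at it. Prm1 is at 28545 in DUKs and 8576 in DU6; Svs4 is above the floor in DBA alone, at 42807.

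For the test of both sides, DU6 and DU6i against DUKs and DBA, the gene with the largest smallest difference among those higher in DU6 and DU6i was Hfe, a regulator of iron uptake, with signals of 8183 and 8227 against values under the floor in DUKs and DBA. Slc6a13, a transporter of GABA and taurine, had 3987 and 6785 against 1260 and 1568. The basement membrane gene Nid2, the matrix gene Thbs2, the secreted Wnt modulator Sfrp2, the chemokine Ccl6 and the muscle myosin light chain Myl1 were also higher in both DU6 lines, Sfrp2 by 2.22-fold and 2.40-fold in the 2 pairs. Lower were H2-Eb1, a class II MHC chain, with 8627 in DUKs and 12279 in DBA and under the floor in DU6 and DU6i, the mitotic kinase Plk1, the glucose transporter Slc2a3, the gluconeogenic enzyme Fbp1, Ldhc and Iigp1. A second probe set of H2-Eb1 gave log2 ratios of -0.21 and -0.46, and one of Slc2a3 -0.90 in DU6 vs DUKs. H2-Ea, another class II chain, was above the floor in DBA alone, at 8566. Class II genes did not all go this way, since H2-Aa was at least 2-fold higher in both pairs.

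By limma, 0 of 5267 probe sets passed an adjusted p of 0.05 between the sides, and 252 had an unadjusted p under 0.05, where 263.4 would be expected by chance. The smallest adjusted p was 0.829. Among the 495 list genes measured, 0 passed when adjusted over the list alone, and 44 had an unadjusted p under 0.05 where 24.75 would be expected. All genes in the plot of both sides were therefore chosen by size. With no filter on low signals, limma passed 5 probe sets.

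**Figure D4:**
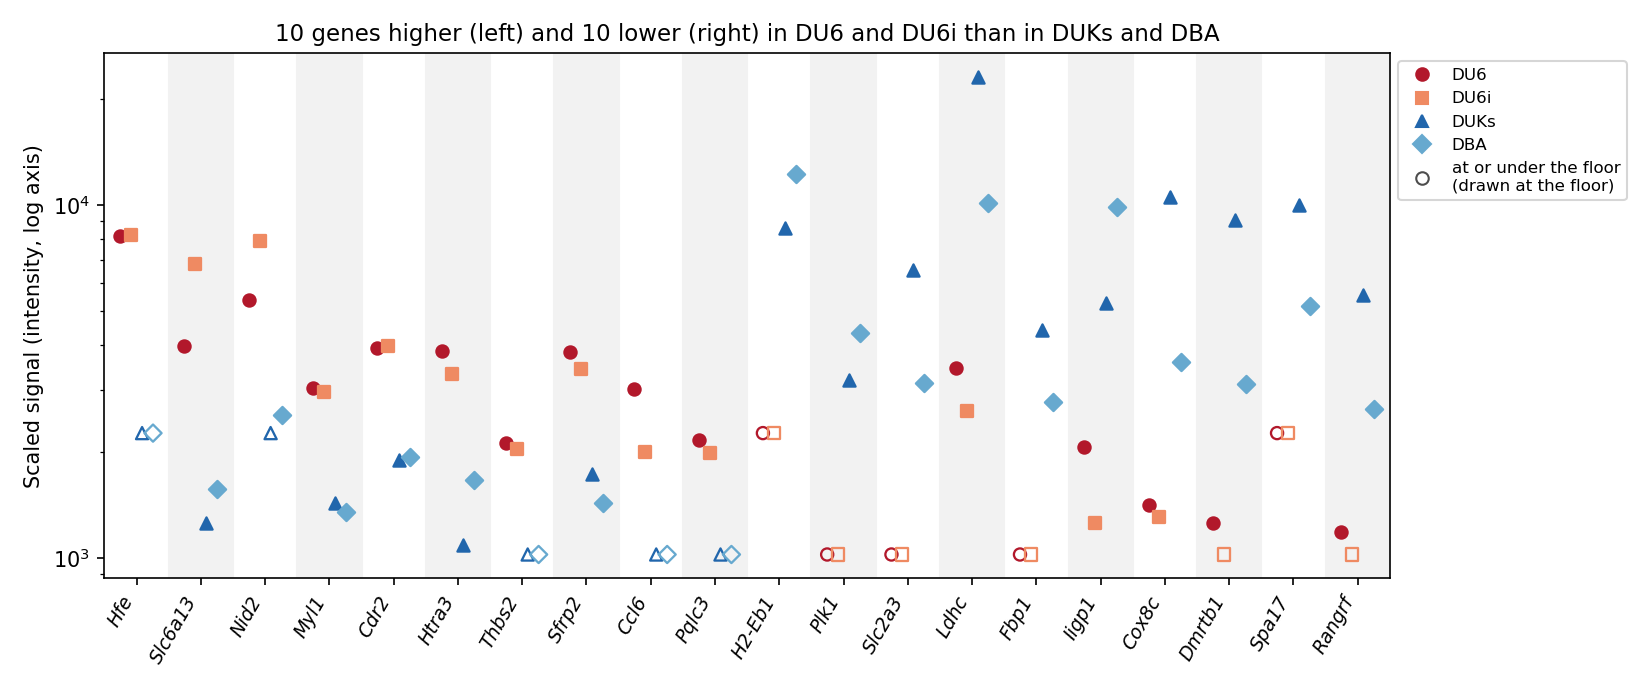
Scaled signal (log axis) per line of the 10 genes higher and the 10 lower in DU6 and DU6i, 1 point per line. Open points lie at or under the floor and are drawn at it. Hfe is at 8183 and 8227 in DU6 and DU6i, and H2-Eb1 at 8627 and 12279 in DUKs and DBA.

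DU6 and DU6i, which are related, lie on different sides of the split in 5' control signal (15.3% and 54.5% on chip A), and their 99th percentiles on chip A were 18810 and 34793. Slc38a5 was 9.55-fold, C4bp 10.7-fold and Lcn2 7.14-fold higher in DU6, and Ifi27 14.3-fold, Rpl41 10.1-fold, the liver glycoprotein gene Ahsg 8.93-fold and Cavin1, of adipocyte caveolae, 6.79-fold lower. In all, 263 probe sets were higher and 312 lower, of 5478 (10.5%). Between DU6 and DBA, which are matched on 5' control signal, 208 were higher and 229 lower, of 5491 (7.96%). Between DU6i and DUKs, the other matched pair, 189 were higher and 377 lower, of 5579 (10.1%). In DU6 vs DU6i the median of mature adipocyte markers was -1.16 and that of epididymis and male tract markers 1.05. Between DUKs and DBA, 342 were higher and 301 lower, of 5691. DUKs was higher for Saa3, an acute-phase gene (6.59-fold), Efhd2 (4.26-fold), Dnajb3 (4.03-fold) and Hspa4l (3.90-fold), and lower for Fgg, a fibrinogen chain (7.08-fold), Emid1 (6.89-fold), Amot (6.83-fold), Egr2 (6.09-fold) and Pfn1 (5.78-fold).

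Genes of adipocyte function chosen before the data were examined fell into groups. Adipoq, Retn, Lpl, Lipe, Fabp4 and Scd1 were highest in DU6i and lowest in DU6. Adipoq, which encodes adiponectin, had signals of 48251 in DU6i, 36670 in DUKs, 28894 in DBA and 21044 in DU6. That is also the order of the 99th percentiles of all chip A signals. Lep went another way, at 27777 in DU6i, 12446 in DU6, 8696 in DUKs and 3837 in DBA. Its log2 ratio of 0.52 in DU6 vs DUKs was near the technical SD of 0.44. Ghr was at 7106 in DU6i, 3710 in DUKs and 1534 in DU6, and under the floor in DBA. On chip B, Fasn was at 61926, 40390, 63666 and 37212 in DU6, DU6i, DUKs and DBA. Slc2a4, the insulin-regulated glucose transporter, was 1.62-fold higher in DU6 than in DUKs. Igf1 had log2 ratios of 0.08 and 0.43 in the 2 pairs. Ucp1 and Insr were not above the floor on any array, and no probe set was named Cfd or Agt here.

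**Figure D5:**
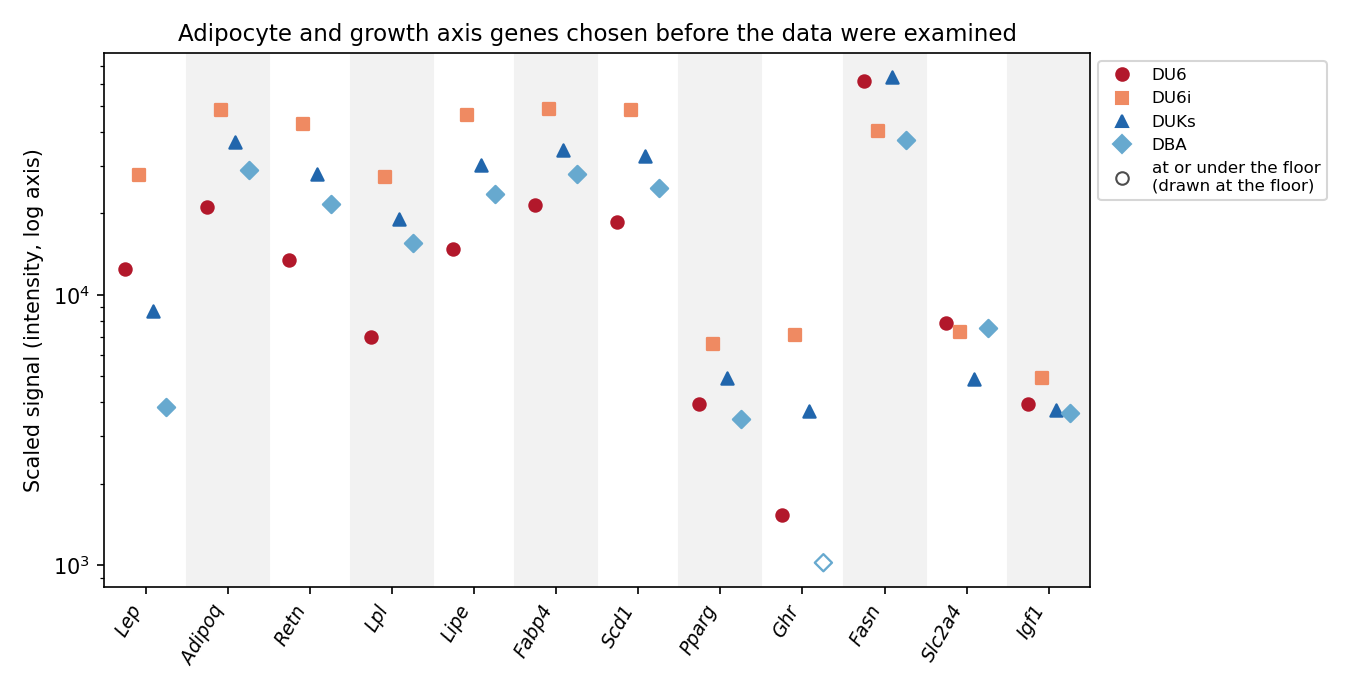
Scaled signal (log axis) per line of the sentinel genes above the floor, 1 point per line; the open point lies under the floor and is drawn at it. Lep runs from 3837 in DBA to 27777 in DU6i, and Adipoq from 21044 in DU6 to 48251 in DU6i.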

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

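The tests of adipocyte genes on chip B, and of the split of DU6 and DBA from DU6i and DUKs by quantile normalisation and by chip B control signal were chosen after the result was seen, as was the count over other splits.

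The following genes were picked out because they were at least 2-fold apart in opposite directions in the 2 main pairs; the difference between the pairs was not tested, since each line has 1 pool. Higher in DU6 than DUKs and lower in DU6i than DBA were, with both log2 ratios in that order, Actb (2.04 and -3.15), Adig (3.09 and -1.22), Amot (1.19 and -3.07), C4bp (1.17 and -3.50), Egr2 (1.20 and -2.84), Elovl6 (1.12 and -1.02), Emid1 (1.45 and -3.24), Fmod (1.66 and -1.59) and Slc1a1 (1.19 and -3.30). The opposite held for Ghr (-1.27 and 2.80), Ifi27 (-3.43 and 1.08), Igfbp7 (-1.06 and 1.103), Mup5 (-1.52 and 1.26), Nr2c2ap (-2.66 and 1.28), Pgam1 (-1.73 and 1.30), Raly (-1.47 and 1.94), Rpl41 (-1.57 and 2.20), Sptbn1 (-1.24 and 2.23) and Timp2 (-1.27 and 1.21). Where a signal was at or under the floor, as for Adig in DUKs and Ghr in DBA, the size of the ratio is a lower bound. In all, 85 probe sets were of this kind. Opposite ratios in these pairs add up to a difference of DU6 and DBA from DU6i and DUKs. That is also the split in 5' control signal, so that for these genes a difference between the pairs cannot be told apart from it. The 3' control probe set of actin on chip A, with signals of 19391, 34426, 29305 and 20315 in DU6, DU6i, DUKs and DBA, did not follow Actb, with 16284, 991, 3970 and 9049. The 3', 5' and middle actin controls on chip A gave log2 ratios of -0.60, -0.89 and -0.51 in DU6 vs DUKs. In DU6i vs DBA they gave 0.76, 0.68 and 0.73. On chip B they had the same signs, so that all went against Actb in both pairs. A second Actb probe set, of 8 others, gave log2 ratios of 2.45 and -2.00, in the same directions as the first. The direction for actin thus depended on the probe set, and these ratios do not establish a difference of its transcript.

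The mature adipocyte markers also went opposite ways, with medians of -0.68 and 0.86, a difference that was not tested. In DU6i vs DBA the wider signal range of the DU6i array was argued against as the whole cause, because the chip A adipocyte genes had a median of 0.93 where equally bright probe sets gave medians from 0.12 to 0.76. They also ran with the 5' control signal, low in DU6 and DBA, and in the pairs matched on it their medians were 0.07 in DU6 vs DBA (percentile 66.1) and 0.51 in DU6i vs DUKs (percentile 99.9), the latter 0.18 (percentile 89.4) after quantile normalisation. In DU6 vs DUKs the chip A median of -0.80 lay outside the range of -0.76 to -0.35 for equally bright probe sets by less than its spread of 0.13, so that a lower content of adipocyte transcripts and the narrower range of the DU6 array cannot be told apart. Fewer adipocytes in the DU6 pool stay open as well. The 6 genes on chip B had a median of -0.12 with a spread of 0.18. This median was past the limit set to argue against fewer adipocytes, but by less than its spread. That spread holds the technical error of probe sets alone. After quantile normalisation the chip B median was 0.017. RNA quality, labelling and a difference between the lines stay open too, since 1 pool per line does not separate them.

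Probe sets that separated DU6 and DBA from DU6i and DUKs numbered 2187 of 5267 (41.5%). Fewer separated the sides (1588, 30.2%) or the outbred from the inbred lines (1491, 28.3%). By chance each split would take 33.3%, so that these lower shares lay below chance. No probe set can count for different splits, so a higher share for DU6 and DBA lowers the others. By limma 526 had an unadjusted p under 0.05 for the DU6 and DBA split, against 252 for the sides and 263.4 expected. The smallest adjusted p for this split was 0.446. Scaling or signal range was argued against as the whole cause, because 2135 probe sets still separated this way after quantile normalisation, with 1674 for the next split. A fault of single chip A hybridisations was argued against too, because on chip B the middle control probe set also stayed at or below 14.3% of the 3' signal in both DU6 and DBA. A difference of the pools seen by both chips had what it needs, with 782 probe sets on chip B against 609 for the next split. Whether it arose in the tissue, in the RNA or in its labelling stays open, and no biological explanation was tested, because the labels name no property that DU6 and DBA share.

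Between the sides 0 probe sets passed the threshold, and the highest of the other splits gave 0 as well; 3 of the 3 splits gave as many, which are too few for a share under 0.05.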

How the results depend on the processing

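Pairs matched on 5' control signal, chip B alone, leaving out bright probe sets and the second probe set of a gene were tests chosen after seeing the data. Replicates could not be paired, because each line has 1 array per chip; with the lines paired as DU6 with DUKs and DU6i with DBA, limma passed 0 probe sets, with 180 at an unadjusted p under 0.05. Rescaling to one trimmed mean moved nothing, since all arrays already had the same one. Quantile normalisation kept every 2-fold count within 1.5 times. Counts higher and lower are given for DU6 vs DUKs, DU6i vs DBA, DU6 vs DU6i and DUKs vs DBA in that order, followed by those shared by both main pairs as higher, lower and opposite. With the floor halved they were 368 and 612, 474 and 637, 475 and 552, 591 and 511, then 33, 82 and 180. With the floor doubled they were 98 and 170, 147 and 180, 121 and 177, 171 and 144, then 6, 17 and 46. At 3-fold they were 35 and 114, 74 and 102, 64 and 84, 81 and 68, then 2, 8 and 13. With plain _at probe sets alone they were 34 and 52, 39 and 57, 51 and 33, 60 and 40, then 2, 2 and 10. A stricter fold and fewer probe sets lower a count by construction, as a doubled floor shrinks every ratio against it. With log2(signal + floor), 108 were higher in DU6 than DUKs, 168 lower in DUKs than DBA, and 6, 24 and 52 shared. With both arrays above the floor, 207 were lower in DU6 than DUKs, 230 lower in DU6i than DBA, 170 higher in DU6 than DU6i, and 24 lower and 48 opposite in the main pairs. Without probe sets brighter than 10000, 169 were higher in DU6i than DBA. In the matched pairs 26 were higher in both, and 4 gene lists were low in both. The number of lists low in both was 1 with the floor halved, where the epididymis and male tract list was not, and 1 on chip B alone, where the testis and germ cell list was not (percentile 3.07 in DU6i vs DBA, 3 genes) and 0 were high in both. Between the sides limma passed 0 in each setting and with each line left out (0 to 0, the lone line of a side assumed to vary like the other side), but 5 with no filter, where probe sets set to the floor on all arrays add zero variances. The direction reversed for the lymphocyte list in DU6 vs DUKs on chip B alone (0.94), for the 3 sentinel genes measured there (0.0842), for ribosomal proteins with quantile normalisation (0.0471), by a second probe set for Akap1 (0.12), Ccnd3 (0.0284), Dmrtb1 (0.28) and Dnajb1 (0.26) in DU6 vs DUKs, and for Pdxdc1 in DU6i vs DBA by a second probe set (-3.42) and by the mean of all (-0.71). Apart from construction, the cause was not tested. Signal over background limits these arrays, with at most 51.1% of probe sets above the floor on chip A and 27.9% on chip B.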

Other observations

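The second germ cell list was fixed before its values were seen; the tests by quantile normalisation and against the epididymis list were chosen after the result was seen.

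Genes of oxidative phosphorylation had medians of 0.16 in DU6 vs DUKs (percentile 87.0) and 0.12 in DU6i vs DBA (percentile 66.04), and Cox8b, a subunit of cytochrome c oxidase, was at least 3.58-fold higher in DU6 than DUKs. Fatty acid oxidation genes were higher in DU6 in 14 of 15 (median 0.35, percentile 93.8) and in DU6i in 9 of 15 (median 0.33, percentile 96.9); the second lay above the limit after quantile normalisation (percentile 98.9), and the first on chip A alone (0.43, percentile 98.6). Glycolysis genes had medians of 0.14 and 0.04, insulin signalling genes 0.14 and 0.04, and genes of the growth hormone and IGF axis 0.02 and -0.02. Gys1, the glycogen synthase, was 2.56-fold higher in DU6 than DUKs. Fabp3, a fatty acid carrier of muscle and brown fat, was 4.36-fold lower. Cholesterol synthesis genes had medians of 0.00 and 0.02, and Scarb1, the receptor for high-density lipoprotein, was at least 3.15-fold lower in DU6 than DUKs. With the floor and scaling used throughout and both chips together, these lists lay inside the central 95% of random lists in both pairs, which does not show that their genes were equal.

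Stress and growth lists lay inside as well. Antioxidant and xenobiotic genes had medians of -0.09 and 0.02, with members on both sides: Gsto1, a glutathione transferase, was higher in both pairs (log2 ratios of 1.08 and 1.25), whereas Sod1 and Sod2, the superoxide dismutases, were higher in DU6 than DUKs alone (1.55 and 1.09). Heat shock genes had medians of 0.06 and -0.12, with the chaperone gene Hsp90aa1 at -1.03 in DU6 vs DUKs. Cell cycle genes had medians of 0.10 and -0.25. Nerve and Schwann cell markers had medians of 0.36 (percentile 92.5) and -0.58 (percentile 2.83), and Erbb3, a receptor of Schwann cells, was at -1.45 in DU6i vs DBA. The class II gene H2-Ea was above the floor in DBA alone, whereas the class II gene H2-Aa was at least 2-fold higher in both main pairs. Psmb9, a subunit of the immunoproteasome, was 3.39-fold lower in DU6i than DBA, and the list of antigen presentation genes had a median of -0.16 there.

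A hypothesis for the germ cell transcripts was that cells of the testis had been carried into the fat pools to different degrees. A second list of 91 germ cell genes, of which 14 were measured in DU6 vs DUKs, had a median of -0.63 there (percentile 0), which carry-over needs. Only 3 of the 14 were above the floor on both arrays, so most of these ratios are bounds. In DU6i vs DBA 6 genes were measured, with a median of -0.35 (percentile 23.3), where the prediction asked only for a negative median. Any source of germ cell transcripts would move this list with the first, so that it does not single out carry-over. Array scaling was argued against, because the first list's median stayed at -1.74 in DU6 vs DUKs after quantile normalisation. A single common source for germ cell and epididymal transcripts needs both lists to shift alike. Between DU6 and DU6i the epididymis median (7 genes) exceeded the germ cell median (10 genes) by 0.66. Of these genes, 6 of the 7 and 7 of the 10 were above the floor on both arrays. The spread of 0.23 set beside the gap holds the technical error of probe sets alone, not differences between genes or pools. The gap argues against a single source only within that limit. Whether the lines differed in the age at which germ cells mature, in tissue dissected with the fat, or in expression within fat was not tested.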
